A study of Arabidopsis thaliana with 6 samples.

How the data were processed

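RNA from flower buds of Arabidopsis thaliana, Columbia background, was sequenced in 6 libraries. The plants were wild type or carried a mutation of CEP1, a papain-like cysteine protease (atcep1). Buds were sorted into 3 classes by anther development stage, called A (anther stages 5 to 6), B (7 to 9) and C (10 to 11), and each genotype was sequenced once per class. Per the labels' protocols, messenger RNA was enriched from total RNA on oligo(dT) beads, fragmented, copied from random hexamers, amplified by PCR and read on an Illumina HiSeq. Nothing in the labels describes a kit that marks strand, so reads from a gene and from an antisense partner cannot be told apart.

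The authors deposited 1 table per library. Per the file headers, each row is a transcript model with its count of uniquely mapped reads, its length, the percent of the model covered and its RPKM. The deposited counts are whole numbers whose sum equals the total given in the header of each file. The deposited RPKM values equal the count divided by the model's length and by that total, up to the usual scaling. The percent covered was used only to describe CEP1. TAIR10 is the genome build named in the submitters' processing notes; the aligner and the counting program are not given in the sources used here. Models without a read are not listed, and were set to a count of 0. Models read by 1 read were covered over a median of 49 bases.

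The totals were 4037584, 4100078 and 4247731 reads for wild-type stages A, B and C, and 4135822, 4162141 and 4411953 reads for atcep1 stages A, B and C. At these depths 3 reads on CEP1, taken as the floor, correspond to 0.441 to 0.482 RPKM. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

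Counts and RPKM of the 30088 models listed in any library were summed to 25964 loci, of which 19237 had a read in all 6 libraries. Reads that fit more than 1 model appear to be missing from these unique counts: protein-coding loci with 1 RefSeq transcript had a median mean RPKM of 10.8 (13772 loci), and those with 2 or more had 2.81 (10045 loci). Whether missing reads cause this difference was not tested, and levels of genes with several isoforms may be too low; 314 of the 322 loci on the gene lists had a read. Symbols and coordinates were taken from the files. The reference annotation (TAIR10.1) was used for symbols the files lack, with 25743 loci matched, and for GC content.

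The test of genotype used edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr on the genotype groups, quasi-likelihood F test) with stage and genotype as additive terms, so that each atcep1 library is set against the wild-type library of its own stage. It had 2 residual degrees of freedom and tested 16114 genes. The steps from A to B and from B to C came from the same fit. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The labels give no second library of any genotype and stage, so the spread in these tests is how far the genotype difference varies between stages; a difference limited to 1 stage counts as noise, and the interaction of genotype and stage has no residual degrees of freedom. Nothing says whether libraries came from separate plants. SEs were computed as the log2 fold change divided by the square root of F.

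Within a stage, 1 library was set against 1 library with no test. The value was log2((atcep1 RPKM + 1)/(WT RPKM + 1)), and a gene was counted as at least 2-fold different when this was at least 1 or at most -1 and the higher RPKM was at least 5. This scale understates the change of low genes. Ratios of reads per library total carry an exact conditional 95% binomial interval.

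A total of 19 gene lists with 322 loci were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, when at least 3 members were tested. With an estimated correlation camera rests on the 2 residual degrees of freedom, so passing was unlikely in advance for any list. Within a stage, a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, over members with a mean RPKM of at least 1.

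Named genes are CEP1; for genotype, the 10 largest rises and 10 largest falls among called genes with the same sign at all 3 stages and a mean RPKM of at least 5; for each stage, the 5 largest and 5 smallest log2 ratios among genes whose higher RPKM is at least 10; for each step, the 6 largest rises and 6 largest falls called with the same sign in both genotypes and a mean RPKM of at least 5; and for each list up to 4 called members by size. Transposons, chloroplast and mitochondrial genes and ribosomal RNA were left out of the named genes.

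The alternatives were DESeq2 1.42.0, library totals without TMM factors, no filter on low counts, limma with a trend on log2(RPKM + 1) and log2(RPKM + 0.1), no stage term, each stage or library left out, and, within a stage, other pseudocounts, filters and scalings. Models kept apart, organelle transcripts left out and a correction for GC content and length were added after the data were seen, as was the enrichment of GO processes (terms with 10 to 500 of the 9380 tested nuclear genes that carry one).

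The scripts were tested on simulated data. For genotype, with 50 changed genes at each fold among the 15803 tested, 32% of those changed 1.5-fold, 74% of those changed 2-fold, 92% of those changed 4-fold and 98% of those changed 8-fold were called, with 7 unchanged genes among 155 calls. For the step from A to B, over 15850 genes, the shares were 12%, 62%, 86% and 88%, with 6 unchanged genes among 130 calls. In these simulations few genes changed, and no genotype difference varied between stages. Counts were drawn at the dispersion trend alone, so the shares and false calls may differ in the real data. Of 200 unchanged random lists, 6% fell outside the 2.5th to 97.5th percentile. Being random, these lists do not show how often a list of genes that vary together falls outside.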

Results

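Transcripts of flower buds were counted in 6 libraries, 1 for each of 2 genotypes at 3 classes of anther development. Wild-type plants were compared with atcep1 plants, whose mutation lies in a papain-like cysteine protease gene. Stage A covers anther stages 5 to 6, stage B 7 to 9 and stage C 10 to 11. There was 1 library per genotype and stage, so a value at a single stage has no replicate check. On log2(RPKM + 1) of 18100 genes, the first principal component held 57.7% of the variance and ordered the libraries by stage within each genotype, and the second held 26.5% and parted the genotypes. On the first component each atcep1 library also lay further in the direction of later stages than the wild-type library of its stage (-46.7 against -84.3 at A, 14.9 against -9.33 at B and 82.1 against 43.4 at C).

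CEP1 itself was at or near the floor of detection in every library. The gene (AT5G50260) lies on chromosome 5 at 20455317 to 20457029 (TAIR10, plus strand), with 1 transcript model of 1541 nucleotides. It had 0, 1 and 6 reads in wild-type stages A, B and C, or 0, 0.158 and 0.917 RPKM. In atcep1 it had 4, 5 and 6 reads, or 0.628, 0.780 and 0.883 RPKM. At stage C the 95% Poisson interval of either count was 2.20 to 13.1 reads, and the reads covered 15.2% of the model in wild type and 11.4% in atcep1. The gene was too low to be tested, and its level could not check the genotype labels at this depth. None of the 1436 windows of 49 bases within its exons in the reference annotation had an exact match elsewhere in the reference genome (0%). Windows across exon junctions and near matches were not searched.

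The main comparison asked which transcripts differ between atcep1 and wild-type buds across the 3 stages. By camera with a preset correlation, the lists of exine, tapetal secretory, pollen coat and pollen genes were higher in atcep1. Those of meiosis and cell division were lower. With an estimated correlation 0 lists passed, which was likely in advance at 2 residual degrees of freedom. The tapetum is the anther cell layer that feeds pollen. Of 16114 genes tested, 2573 were higher and 1859 lower in atcep1 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3 libraries per genotype). The balance of directions depended on the scaling, with 2256 higher and 2238 lower from library totals without TMM factors. Without stage A, 2323 genes were called, and with DESeq2 2236. Of the genes called without stage C, 89.3% had the same sign at stage C, and the share was 95.2% at stage A and 96.1% at stage B for those called without that stage.

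The 10 largest rises were of genes with few reads in the wild-type stage A library. AT3G21990, a DUF26 protein gene, had 0, 6 and 10 reads in wild-type stages A, B and C and 21, 181 and 379 in atcep1 (log2 fold change 5.18, SE 0.25, adjusted p = 1.99e-05). The phosphate transporter gene PHT1;7 went with it (5.09, SE 0.31), as did the sugar transporter gene ATSTP6 (4.58, SE 0.24), the lipase-like gene AT1G20130 (4.45, SE 0.21) and the amino acid transporter gene AT1G71680 (4.22, SE 0.35). The others were AT2G04115 (4.18), AT4G10603 (4.16), the glycosyl hydrolase gene AtGH9B15 (4.11), the ribonuclease gene RNS3 (4.04) and AT2G01422 (3.97), the last at 10, 7 and 14 reads in wild type and 169, 151 and 162 in atcep1. Without stage C the value was 5.78 for PHT1;7 and 6.21 for AT1G71680. RNS3 had 0 reads in wild-type stages A and B, where the 95% lower bounds of its read ratio were 2.98 and 9.13. Its value of 7.62 without stage C therefore rests on no wild-type read. The falls of genes with the same sign at all 3 stages were smaller. Among them the small heat shock protein gene HSP17.6II fell most (log2 fold change -2.37, SE 0.25, adjusted p = 3.99e-04), followed by the cold-response regulator CBF3 (-2.32), AT3G16300 (-2.09), AT1G05550 (-2.08), the histone gene HTR11 (-2.06) and the photoperiod gene ADO3 (-1.99). A small nucleolar RNA gene, AT4G39364 (-1.97), AT2G07835 (-1.95), HSP17-6C (-1.94) and AT1G06420 (-1.81) completed them. Without stage A, AT2G07835 (-1.35, adjusted p = 0.103) and HSP17-6C (-1.57, adjusted p = 0.0524) were no longer called. AT2G07835 stood at -2.55 without stage C, and ADO3 at -2.69 without stage B.

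Sporopollenin and exine genes, which build the outer pollen wall, rose together: 13 of 15 tested members were higher and 0 lower, both over all genes and adjusted over the list alone. The list median was 1.75 (camera adjusted p = 5.66e-06, adjusted p = 0.263 with an estimated correlation). SHT, a spermidine hydroxycinnamoyl transferase gene, rose by a log2 fold change of 3.22 (SE 0.16), CYP703A2 by 2.85 (SE 0.27), MS2 by 2.13 (SE 0.17) and PKSB by 2.04 (SE 0.28; 2.64 without stage A). Of the tapetal secretory and callose-tetrad genes, 7 of 8 were higher and 0 lower, also adjusted over the list alone, with a median of 1.75 (camera adjusted p = 1.48e-04, adjusted p = 0.410 with an estimated correlation, fry adjusted p = 0.0650). ATA20 rose by 3.78 (SE 0.18), the glucanase-like gene A6 by 3.30 (SE 0.47; 3.96 without stage A and 2.70 without stage C), ATA1 by 2.86 (SE 0.31) and A9 by 2.04 (SE 0.24). Pollen coat genes were higher in 11 of 12 cases, with 0 lower, also adjusted over the list alone (median 1.88, camera adjusted p = 6.09e-08, adjusted p = 0.264 with an estimated correlation). Among them were GRP20 (2.34, SE 0.20), the wax synthesis gene CER6 (2.20, SE 0.17), ABCG31 (2.18, SE 0.18) and EXL3 (1.93, SE 0.14).

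Tapetum regulators moved both ways. Of 15 tested, 4 were higher and 4 lower, and 5 and 4 adjusted over the list alone; the list passed no test (median 0.37, camera adjusted p = 0.450). The higher members were MYB99 (2.08, SE 0.34), MS1 (1.36, SE 0.31), AMS (1.24, SE 0.12) and BHLH091 (1.17, SE 0.28). The 4 lower members were smaller in size and so are not named, and the lowest value in the list was -1.11. Without stage A, MS1 was no longer called (adjusted p = 0.0828), and without stage B neither was BHLH091 (adjusted p = 0.0507).

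Pollen genes were higher in 14 of 25 cases and lower in 0, or 17 and 1 adjusted over the list alone (median 0.80, camera adjusted p = 1.90e-06, adjusted p = 0.321 with an estimated correlation, fry adjusted p = 0.0585). The proton pump gene AHA6 rose by 3.23 (SE 0.13), TIP1;3 by 3.08 (SE 0.25), ADF7 by 2.02 (SE 0.28) and AGL66 by 1.95 (SE 0.34). All 5 tested members of the secondary wall and dehiscence list rose, also adjusted over the list alone (median 1.83, camera adjusted p = 4.86e-05, adjusted p = 0.263 with an estimated correlation): LAC4 by 3.06 (SE 0.16), CESA8 by 1.89 (SE 0.19), CESA7 by 1.83 (SE 0.18) and CESA4 by 1.71 (SE 0.13) were the named ones. Of the jasmonate synthesis and stamen maturation genes, 10 of 22 were higher and 0 lower, and 11 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 1.14e-04, adjusted p = 0.263 with an estimated correlation). They included MYB24 (1.39, SE 0.27), LOX3 (1.38, SE 0.11), LOX2 (1.35, SE 0.12) and MYB108 (1.09, SE 0.30). Without stage C, MYB24 (adjusted p = 0.102) and MYB108 (adjusted p = 0.184) were not called, and without stage B MYB108 was not (adjusted p = 0.0734).

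Of the papain-like cysteine proteases, the family of CEP1, 8 of 16 were higher and 1 lower, and 8 and 2 adjusted over the list alone (median 0.43, camera adjusted p = 0.0181, adjusted p = 0.264 with an estimated correlation). THI1 rose by 3.63 (SE 0.21), RD21C by 2.19 (SE 0.18), the xylem peptidase gene XCP2 by 1.72 (SE 0.18) and RD19C by 1.41 (SE 0.14). Other cell death proteases and nucleases were higher in 10 of 14 cases, with 0 lower, and 10 and 1 adjusted over the list alone (median 1.08, camera adjusted p = 4.21e-04, adjusted p = 0.264 with an estimated correlation). RNS3 led them (4.04), followed by the aspartic protease gene PASPA3 (3.08, SE 0.43, and 2.36 without stage B), DMP4 (2.88, SE 0.41) and RNS1 (2.68, SE 0.23).

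Cell division genes fell in 13 of 15 cases and rose in 0, or 14 and 0 adjusted over the list alone (median -0.64, camera adjusted p = 3.59e-07, adjusted p = 0.263 with an estimated correlation). CYCB2;1 (-1.41, SE 0.25), CYCB1;4 (-1.10, SE 0.12), the cytokinesis syntaxin gene KNOLLE (-0.93, SE 0.11) and CYCB2;3 (-0.74, SE 0.15) fell most. Without stage A, CYCB2;3 was not called (adjusted p = 0.0855). Of 24 meiosis genes, 6 were lower and 0 higher, or 3 and 0 adjusted over the list alone (median -0.48, camera adjusted p = 5.64e-05, adjusted p = 0.264 with an estimated correlation, fry adjusted p = 0.0650). HEI10, a crossover gene, fell by 1.56 on the log2 scale (SE 0.17), SDS by 1.01 (SE 0.32), DMC1 by 0.77 (SE 0.13) and OSD1 by 0.58 (SE 0.16). SDS was not called without stage A (adjusted p = 0.225) or without stage B (adjusted p = 0.190), and OSD1 was not without stage A (adjusted p = 0.219).

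With fry the adjusted p was 0.0168 for the exine, pollen coat, papain-like protease and jasmonate lists and 0.0123 for the cell death, secondary wall and cell division lists. The photosynthesis, carpel, floral meristem, heat shock, wound and cold, clock and endoplasmic reticulum lists passed neither camera nor fry across genotypes. Of 18 photosynthesis genes 5 were lower, led by FBP (-1.43, SE 0.25), with LHCB1.2 (-0.61), LHCB4.1 (-0.41) and RBCS1B (-0.38); these last 3 were not called without stage A or without stage B. Of 11 carpel and ovule genes 2 were lower, INO (-1.43, SE 0.25) and ANT (-0.81, SE 0.09). Of 8 floral meristem genes 4 were higher: the stem cell regulator WUS (1.54, SE 0.43, with 2.28 without stage A and 0.95 without stage C), CAL (0.83, SE 0.21), AP1 (0.66, SE 0.09) and CLV1 (0.47, SE 0.12). CAL was not called without stage A or B, nor CLV1 without stage A. Heat shock genes went both ways, 3 up and 3 down: HSP101 rose (1.28, SE 0.22), and HSP17.4 (-1.61, SE 0.33) fell with HSP17.6II and HSP17-6C. Without stage A, HSP17.4 was not called (adjusted p = 0.0549), and without stage B it stood at -2.23. Among wound, touch and cold genes WRKY33 rose (0.57, SE 0.10), and CBF2 (-3.71, SE 0.52), CBF3 and ERF5 (-0.79, SE 0.23) were among the 4 that fell. The fall of CBF2 rests on stages A and B, with a log2 ratio of 0.33 at stage C. ERF5 was not called without stage A (adjusted p = 0.273) or stage B (adjusted p = 0.109). Of 11 clock genes 3 were lower, namely ELF4 (-1.49, SE 0.33, and -2.19 without stage B), CCR2 (-1.35, SE 0.22) and PRR5 (-0.98, SE 0.12). Of 7 endoplasmic reticulum folding genes SHD (1.26, SE 0.29) and BZIP28 (0.45, SE 0.09) rose and CRT1 fell (-0.58, SE 0.10). SHD was not called without stage A (adjusted p = 0.0825), nor BZIP28 without stage B (adjusted p = 0.0554). The defence genes PR2 (2.25, SE 0.38) and PR5 (1.96, SE 0.30) rose, in a list with too few tested members for camera.

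Transcripts of the organelle genomes differed as well. Chloroplast genes took 1.61%, 1.65% and 1.10% of the reads in wild-type stages A, B and C and 0.851%, 0.757% and 0.696% in atcep1. Mitochondrial genes took 0.330%, 0.506% and 0.322% in wild type and 0.144%, 0.165% and 0.179% in atcep1. With organelle transcripts left out, 4418 genes were called between the genotypes.

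**Figure D1:**
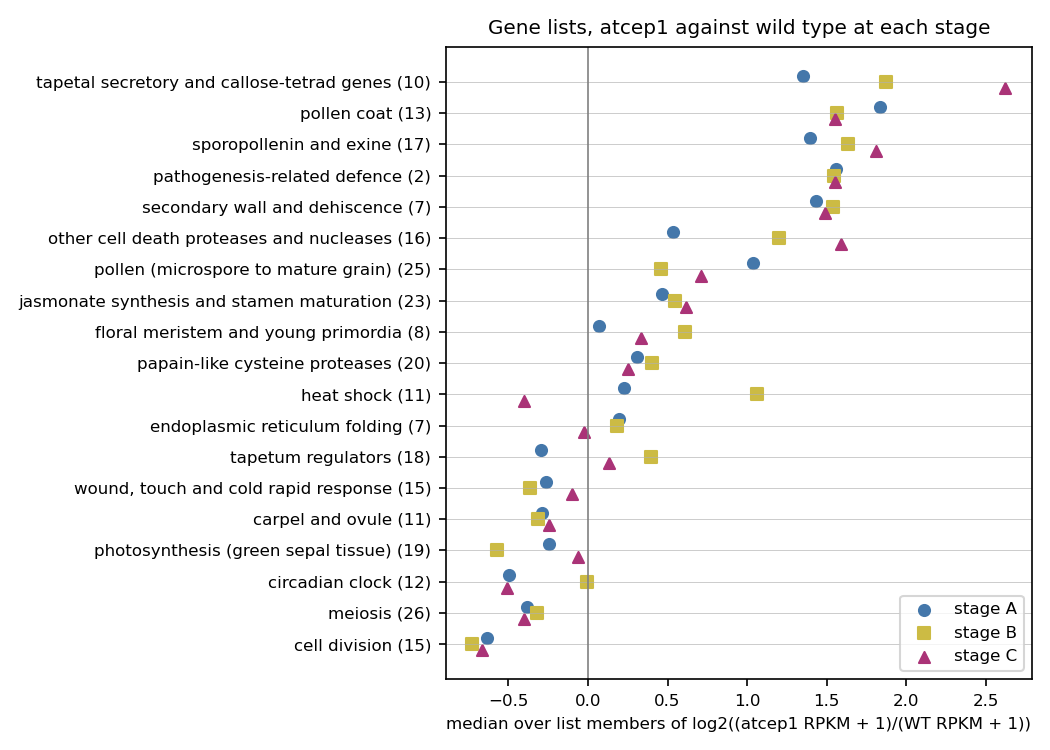
Median over list members of log2((atcep1 RPKM + 1)/(WT RPKM + 1)) for each of the 19 gene lists (number of members in brackets) at stages A, B and C, 1 library per genotype and stage. The tapetal secretory list lies at 1.35, 1.87 and 2.62 and the cell division list at -0.63, -0.73 and -0.67.

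Within single stages, the question was at which stage class the atcep1 library departs from the wild-type library. At stage A, 822 genes were at least 2-fold higher and 429 at least 2-fold lower in the atcep1 library. At stage B there were 897 and 540, and at stage C 1107 and 528. A set of 319 genes was higher and 89 lower at all 3 stages. At stage C the median log2 ratio of genes with at least 5 RPKM in both libraries was -0.11; centred on it, 1264 genes were higher and 362 lower.

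At stage A the largest ratios were of the lipase-like gene AT1G20130 (38.4 against 1.44 RPKM), the pectin lyase-like gene AT3G07820 (32.1 against 1.06), the pectate lyase gene AT3G01270 (39.6 against 1.64), the Ole e 1 family gene AT1G29140 (39.8 against 1.75) and the polygalacturonase gene PGA4 (89.5 against 5.53). The read ratio of PGA4 was 16.2 (95% interval 11.6 to 23.2) at stage A and 2.30 (2.22 to 2.38) at stage C. The lowest ratios were of CBF1 (3 against 98 reads, ratio 0.0299, 95% interval 0.00606 to 0.0899), CBF2 (2.56 against 54.8) and HSP22 (0 against 47 reads, 95% upper bound of the read ratio 0.0797). With them were AT2G07835 and the small nucleolar RNA gene AT5G58595, the last resting on 4 reads.

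At stage B AT1G71680 stood highest (48.2 against 0.646 RPKM), with AT2G04115 (96 against 2 reads, ratio 47.3, 95% interval 12.7 to 396) and AT3G21990 (46.4 against 1.56). Next to them were LCR33 (19 against 0 reads, 95% lower bound of the read ratio 4.60) and FLA14 (49 against 0 reads, 95% lower bound 12.6). CBF1, CBF2 and CBF3 were lowest, at log2 ratios of -3.86, -3.42 and -2.47, followed by AT3G16300 (-2.46) and AT5G60140 (-2.39).

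At stage C A6 stood highest on the scale of log2(RPKM + 1), at 5.90, with 740 reads in atcep1 and 5 in wild type (ratio 142, 95% interval 60.8 to 440). The senescence protease gene SAG12 had 168 reads against 1 (log2 ratio 4.72, read ratio 162, 95% interval 28.6 to 6426), AT3G21990 379 against 10, AT3G63095 251 against 10 and AT5G16920 195 against 6. The lowest ratios were of genes with few reads, namely the small nucleolar RNA genes AT3G50825, AT2G20721, SNOR108 and AT2G35742 and the uncharacterised gene AT2G24592; SNOR108 had 8 reads in wild type and 1 in atcep1 (ratio 0.120, 95% interval 0.00271 to 0.898). CBF1 and CBF2 did not differ detectably at stage C (4 against 5 and 3 against 5 reads in wild type and atcep1), and CBF3 had 26 against 15 reads (log2 ratio -0.71, read ratio 0.555, 95% interval 0.273 to 1.09).

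As groups, exine genes had median log2 ratios of 1.39, 1.64 and 1.81 at stages A, B and C, pollen coat genes 1.84, 1.57 and 1.55, and pollen genes 1.04, 0.46 and 0.71, each at the 100th percentile of the random lists. Cell division genes lay at or below the 0.01st percentile at every stage. Heat shock genes lay at 0.23, 1.06 and -0.40, but their members went both ways, with 6, 6 and 4 of 11 above 0. Their median absolute log2 ratios were 1.25, 1.59 and 0.96, at the 100th, 100th and 99.97th percentiles. Clock genes lay at -0.50, -0.01 and -0.51, with 5, 5 and 4 of 12 above 0.

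**Figure D2:**
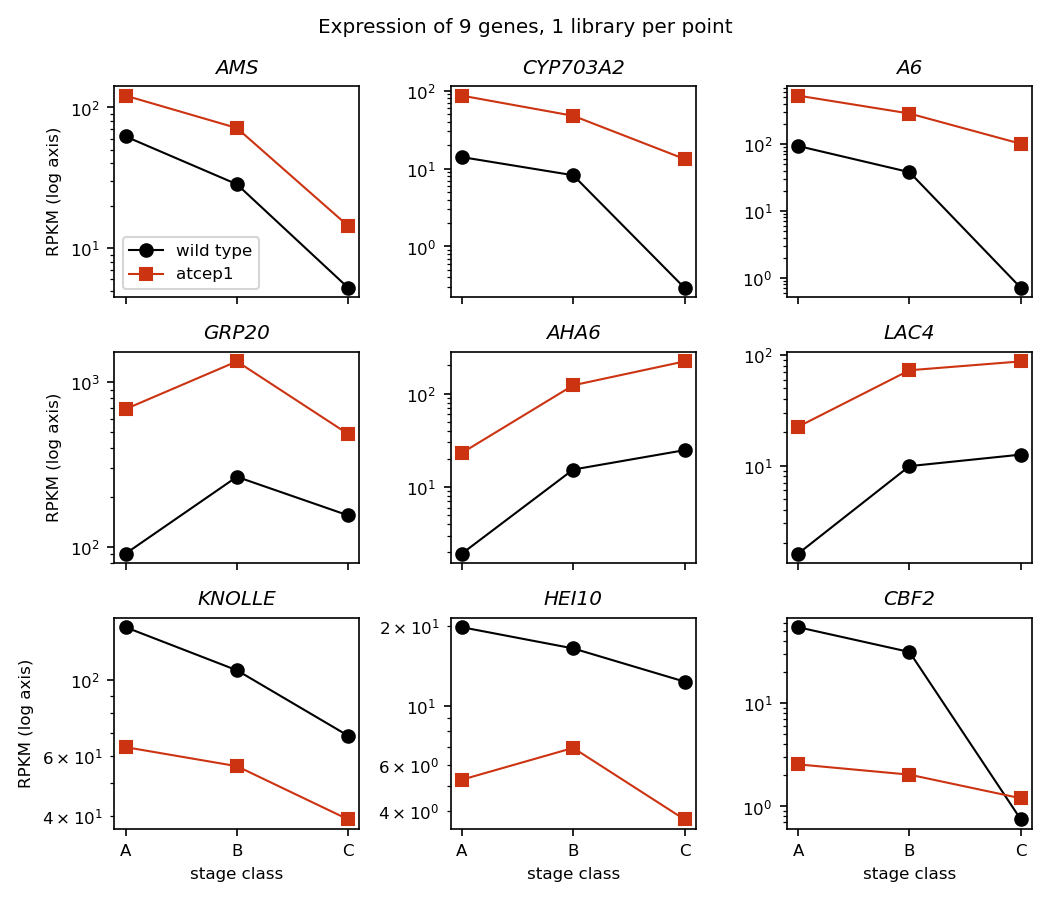
RPKM on a log axis of 9 genes at stages A, B and C in wild type (black circles) and atcep1 (red squares), 1 library per point. A6 fell from 93.5 to 0.708 RPKM in wild type between stages A and C and from 530 to 101 in atcep1, and CBF2 was high in wild-type stages A and B alone.

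The steps between stages describe bud development over both genotypes. Pollen genes rose in both steps and exine and tapetal secretory genes fell, by camera with a preset correlation. With an estimated correlation 0 lists passed, again at 2 residual degrees of freedom. From A to B 702 genes rose and 78 fell, and from B to C 689 rose and 380 fell (edgeR quasi-likelihood test, 2 libraries per stage). In both steps the balance of rises and falls shifted with the library left out. Without the atcep1 stage A library 451 genes were called from A to B, without WT stage C 1577 and without atcep1 stage C 1682; without atcep1 stage B 706 were called from B to C. The 6 largest rises from A to B had 0 reads in both stage A libraries. Their folds were set against 3 reads over those libraries and leave out counting error at stage B. On this scale AT1G75870 was 35.0-fold higher, AT1G25240 27.0-fold, AT2G19000 22.1-fold, AT3G05725 20.4-fold, AT4G15980 19.1-fold and AT5G50040 16.8-fold. The last 2 were not called without the atcep1 stage A library. The falls were led by AT2G21100 (-2.14, SE 0.43), the meristem identity gene LFY (-2.14, SE 0.47), AT5G09780 (-2.09), AT2G32350 (-1.86), AT3G07450 (-1.80) and AT1G04645 (-1.75). Without the WT stage A library none of these 6 was called, with values from -1.07 (LFY) to -1.29 (AT5G09780), and without the WT stage B library only AT3G07450 was. Without the atcep1 stage A library the values were -2.83 for AT2G21100, -3.25 for LFY, -2.86 for AT3G07450, -2.37 for AT1G04645 and -2.45 for AT2G32350, the last not called (adjusted p = 0.0503). Without the atcep1 stage B library LFY stood at -3.07 and AT3G07450 at -2.69.

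From B to C the fatty acid ligase gene AAE11 rose most (log2 fold change 4.08, SE 0.32), with the expansin gene ATEXPA11 (3.62), AT1G44542 (3.41), AT4G11290 (3.36), MLP168 (3.32) and CYP76C3 (3.23). Without atcep1 stage B the values were 2.96 for ATEXPA11, 2.26 for MLP168 and 2.18 for CYP76C3, and without atcep1 stage C 3.14 for AAE11, 2.37 for MLP168 and 2.21 for CYP76C3. AT2G31035 and AT2G32350 had 0 reads at stage C. Against 3 reads over the libraries of that stage they were 9.1-fold and 8.7-fold lower there, with counting error at stage B left out. Their log2 fold changes were -6.78 and -6.71. Without WT stage C, which leaves 1 library at that stage, they were -6.24 and -6.22. AT1G30780 (-4.81), FLA20 (-4.43), ICL (-4.14, SE 0.31) and CBF2 (-3.90) also fell; CBF2 was not called without WT stage C (-0.40, adjusted p = 0.810), and FLA20 was not without atcep1 stage B (-3.28, adjusted p = 0.128). AT1G30780 stood at -3.52 without atcep1 stage B, and CBF2 at -5.37 without atcep1 stage C; AT1G30780 and FLA20 had 0 reads in wild-type stage C. ICL, the isocitrate lyase gene, had 89 reads at stage B and 5 at stage C in both genotypes.

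By list, 20 of 25 pollen genes rose from A to B and 0 fell (median 2.64, camera adjusted p = 3.69e-20, adjusted p = 0.245 with an estimated correlation), and 13 rose and 1 fell from B to C (median 1.17, camera adjusted p = 9.62e-11, adjusted p = 0.267 with an estimated correlation). From A to B the medians of tapetum regulators (-0.57), exine (-0.66) and tapetal secretory genes (-0.95) were already below 0 (camera adjusted p = 3.56e-05, 6.44e-04 and 0.00645, adjusted p = 0.276, 0.245 and 0.472 with an estimated correlation), with 2, 1 and 1 members called lower. From B to C 13 of 15 exine genes (median -2.17) and 7 of 8 tapetal secretory genes (median -2.51) fell (camera adjusted p = 1.20e-10 and 5.56e-09, adjusted p = 0.267 and 0.303 with an estimated correlation), as did 8 of 15 tapetum regulators (median -1.51, camera adjusted p = 7.34e-07, adjusted p = 0.267 with an estimated correlation). Pollen coat genes were higher in 4 of 12 cases from A to B (median 0.60) and lower in 6 from B to C (median -0.75; camera adjusted p = 2.75e-04 and 0.00324, adjusted p = 0.316 and 0.420 with an estimated correlation). Jasmonate and stamen maturation genes rose in 7 of 22 cases from A to B and 8 from B to C (camera adjusted p = 7.56e-06 and 1.20e-10, adjusted p = 0.245 and 0.267 with an estimated correlation). The meiosis list had medians of -0.34 and -0.46 in these steps (camera adjusted p = 7.56e-06 and 4.42e-06, adjusted p = 0.245 and 0.267 with an estimated correlation), with 0 and 1 of 24 members called lower. The cell division list had medians of -0.32 and -0.51 (camera adjusted p = 2.88e-05 and 5.25e-06, adjusted p = 0.245 and 0.267 with an estimated correlation), with 1 and 3 of 15 members called lower, and papain-like proteases 0.51 and 0.35 (camera adjusted p = 0.00228 and 0.00262, adjusted p = 0.245 and 0.267 with an estimated correlation). Of 5 secondary wall genes 4 rose from A to B (median 1.14, camera adjusted p = 9.22e-06, adjusted p = 0.245 with an estimated correlation). Camera also called the cell death, photosynthesis and floral meristem lists from A to B (adjusted p = 0.0113, 0.00228 and 0.0167, adjusted p = 0.316, 0.553 and 0.274 with an estimated correlation). From B to C it called the photosynthesis, wound and cold and endoplasmic reticulum lists (adjusted p = 0.0405, 0.00389 and 0.0342, adjusted p = 0.673, 0.364 and 0.425 with an estimated correlation), none of which passed fry in either step.

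With fry, the adjusted p from A to B was 0.0350 for pollen, jasmonate, papain-like protease, secondary wall and cell division genes, 0.0907 for cell death genes, 0.128 for tapetum regulators, exine and pollen coat genes, 0.161 for meiosis genes and 0.427 for tapetal secretory genes. From B to C it was 0.0386 for exine, jasmonate and cell division genes, 0.0603 for tapetum regulators and papain-like proteases, 0.0872 for tapetal secretory, pollen and meiosis genes and 0.144 for pollen coat genes.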

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

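In this part the splits of the libraries, the tests of GC content and length, of exine and tapetal genes against staging, of anther share, of green tissue and of the CBF genes at stage C were chosen after the result was seen; so were the bound on size in the test of RNA without a poly(A) tail, the correlations within single lists, the clock values with 1 gene left out and the least number of reads asked of CBF genes.

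Tapetum regulators differed in median between stages A and B, with members going both ways at each. The median log2 ratio of atcep1 to wild type was -0.30 at stage A (1.29th percentile of random lists, 7 of 18 members above 0) and 0.39 at stage B (99.1th percentile, 10 of 18 above 0). The difference between the stages was not tested, since each value rests on 2 libraries.

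The higher tapetal and pollen genes and lower meiosis and cell division genes in atcep1 form the first pattern. The real grouping called 4432 genes and the highest of the other splits 0. In the other splits the genotype difference entered the spread, so few calls were likely in advance. With 1 of 10 splits as large, and 1 of the 4 that part every stage as the design does, the splits are too few for a share under 0.05. GC content and gene length as the whole cause are argued against, since after correction the medians were 1.80 for exine, 2.02 for tapetal secretory, 0.86 for pollen, -0.53 for meiosis and -0.63 for cell division genes and 5 of 5 lists passed camera at the preset correlation; before correction none of them passed with an estimated correlation (adjusted p from 0.263 to 0.410). Buds further advanced in atcep1 would lower the exine and tapetal secretory genes if these fall steadily. From A to C 22 of 23 fell, yet their median by genotype was 1.75 with 22 above 0. Most of the fall came from B to C (list medians -2.17 and -2.51, against -0.66 and -0.95 from A to B). Levels within a class were not measured, so at A and B the values cannot decide. At stage C the list medians of the log2 ratio were 1.81 and 2.62. These argue against more advanced buds as the whole cause for these genes there, with 1 library per genotype. For pollen, meiosis and cell division genes the same idea stays open. Spearman rho between changes from A to C and by genotype was 0.630 over 64 members pooled (0.268 over all tested genes). Within pollen, meiosis and cell division genes it was -0.22, 0.23 and 0.35, so the pooled value mostly repeats the directions of the lists. A larger share of anther tissue as the only cause would not lower meiosis genes if these were expressed mainly in anthers. Of 24 meiosis genes, 6 were called lower and 0 higher (fry adjusted p = 0.0650). This cannot decide, since where in the bud they were expressed was not measured. Their list medians were only -0.34 from A to B and -0.46 from B to C. The SD of 1.01 among exine and tapetal genes was above their median SE of 0.243. The SD cannot decide either, since members may differ in how far they are expressed outside the anther. A mutation effect, more advanced buds as part of the cause and a larger anther share, alone or beside another cause, all stay open. With 1 library per genotype and stage, any other difference between the buds or libraries of the genotypes cannot be told apart from the mutation.

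The second pattern is the lower chloroplast (median log2 fold change -1.25, 69 genes) and mitochondrial transcripts (-1.38, 25 genes) in atcep1. Less green tissue as the whole cause is argued against by nuclear photosynthesis genes, whose median was -0.27 (-0.24, -0.56 and -0.04 at A, B and C), short of the -0.62 that was asked, and by the fall of mitochondrial genes; a part in it, at stage B above all, is not excluded. A lower carry-over of RNA without a poly(A) tail would also lower nuclear small RNA genes: 8 of 9 were below 0, as predicted before the value was seen, but their median of -0.34 falls short of the same -0.62, and by stage their medians were -0.12, -0.07 and -0.98 at A, B and C, against -1.19, -1.42 and -0.86 for chloroplast genes. This explanation and an effect of the mutation on organelles cannot be told apart with so few small RNA genes and 1 preparation per library.

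The third pattern is CBF1, CBF2 and CBF3, high in wild-type stages A and B. Their median log2 ratio was -3.92 at stage A, -3.42 at stage B and 0.14 at stage C. CBF3, the only one with at least 10 reads at C, had read ratios of 0.123 (95% interval 0.0668 to 0.211), 0.155 (0.0900 to 0.252) and 0.555 (0.273 to 1.09) at A, B and C, which differ by more than counting error; since variation between libraries of one kind was not measured, a genotype difference of one size at all stages stays open. Another time of day of harvest for wild-type stages A and B was predicted to shift the median absolute log2 ratio of clock genes at A and B and not at C, and it lay at the 96.4th, 96.5th and 99.6th percentiles; the signed median, for which nothing was predicted, lay at the 0.08th, 53.2th and 0.51th. With 1 clock gene left out the percentile of the absolute median ranged from 94.7 to 97.1 at B, below the bound. It ranged from 84.6 to 99.0 at A and from 95.0 to 99.9 at C, on both sides of it. Time of day was therefore not borne out, but at A the result hangs on single genes and does not exclude it.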

How the results depend on the processing

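Of the 86 genes named for genotype, 86 kept their direction and call with library totals and with organelle transcripts left out, 75 with DESeq2 and 11 without a stage term, where stage differences enter the spread. No named gene or list reversed direction under any alternative where it was called. Genes called between genotypes numbered 2236 with DESeq2 (2170 of them shared with the 4432) and 495 without a stage term, and 2323 to 4891 with 1 stage left out. The split into higher and lower genes was 2573 and 1859 with TMM factors, 2256 and 2238 with library totals, 1881 and 1861 with limma on log2(RPKM + 1), 1667 and 1649 on log2(RPKM + 0.1), and 1512 and 724 with DESeq2. From A to B 484 genes were called by limma on log2(RPKM + 1), 457 on log2(RPKM + 0.1), and 451 to 1682 with 1 library left out. From B to C the counts were 591 with DESeq2, 565 and 235 with limma (82 higher and 153 lower in the last), and 706 to 1503 with 1 library left out. A minimum of 1 RPKM, which admits more genes, gave 2198, 2275 and 2533 genes at least 2-fold different at stages A, B and C. With an estimated correlation 0 lists passed in camera for genotype and 0 for the steps, and 10 lists lost their genotype call. At 2 residual degrees of freedom such losses were likely in advance and say little about the lists. Leaving out a stage brought calls for photosynthesis (without stage A and without stage C), floral meristem (without stage A) and wound, touch and cold genes (without stage C). The cause was not tested for these shifts. Models kept apart and a GC and length correction, both added after seeing the data, gave 4457 and 4042 genes for genotype. CEP1, SAG12 and CBF1 had too few reads in too many libraries to enter the test across stages.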

Other observations

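All GO process tests in this part were chosen after the data were seen. Of 304 processes, 35 passed for higher and 9 for lower genes, and only some are named here. Among nuclear genes higher in atcep1, fatty acid biosynthesis held 39 called of 63 tested genes against 12.0 expected (hypergeometric test, adjusted p = 2.24e-11 over 304 processes), peptide transport 22 of 35 (6.67 expected, adjusted p = 2.14e-06) and pollen wall assembly 13 of 15 (2.86 expected, adjusted p = 2.28e-06). Plant-type cell wall biogenesis held 18 of 30 (adjusted p = 5.07e-05). Among genes lower in atcep1, the broad process gene expression came first, with 119 of 480 (52.8 expected, adjusted p = 4.05e-16 by the same test). Nucleosome organization held 31 of 56 (6.16 expected, adjusted p = 7.06e-14), ribonucleoprotein complex biogenesis 34 of 104 (11.4 expected, adjusted p = 2.15e-07) and cell cycle 22 of 50 (5.50 expected, adjusted p = 2.15e-07). Genes of a process are not independent, so these p-values are too small.

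The stem cell gene WUS declined from 44 to 32 and 11 reads over wild-type stages A, B and C, and had 51, 101 and 99 reads in atcep1. SAG12, a marker of senescence, had 0, 0 and 1 reads in wild type and 19, 5 and 168 in atcep1. The clock output gene CCR2 had log2 ratios of -1.64, -0.64 and -1.93 at stages A, B and C, and ELF4 -2.25, -0.52 and -2.11.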
